A study of Mus musculus with 2 samples.

How the data were processed

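Long-read RNA sequencing of the left cerebral cortex of B6CASTF1/J mice aged 18 to 20 months was analysed from 2 libraries of 1 group. For each library the authors deposited a table of whole long-read counts per transcript model and an annotation of those models with their exons. Per the deposited notes, the counts derive from the alignments to mm10 that are listed beside an unfiltered set, with the GENCODE M21 annotation. Per the file headers each table holds the counts of a single library, and the values are whole numbers. TALON is named in the source column of the deposited annotation. The aligner, the error correction, the versions and the filters of the upstream steps are not given in the sources used here, and neither is the sequencing platform or the orientation of reads. Exon numbers, model lengths and coordinates were used as the authors deposited them. The tables list transcripts with at least 1 read, so a transcript missing from a table was taken as 0 reads. The deposited text notes hold no measurement.

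Models named for spike-in RNAs, 1.56% of reads in replicate 1 and 1.32% in replicate 2, were kept out of all mouse totals. Gene counts are the sums over all models given to an annotated gene, including unannotated models of that gene, and models of antisense or intergenic loci were left out of them. CPM is relative to the reads on annotated genes, 774629 and 679147. Weighted by reads, the models had a median length of 2117 and 2193 nt. Unannotated models were matched between the libraries by their chain of introns, and single-exon unannotated models of a gene were pooled. The same intron chain was given different classes in the 2 libraries for 1675 of 24445 shared unannotated chains (6.85%). For that reason class was not part of the matching of transcripts. That choice was made after first results with class in the matching were seen, and the earlier form is kept as an alternative.

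Shares of reads are given with 95% Wilson intervals. Means are given with the SD over the 2 libraries. The limit for a gene with 0 reads is 3 counts of the library's total. Genes with at least 20 reads in total were compared by a two-sided exact conditional binomial test against the library totals, and transcript shares and exon inclusion by Fisher's exact test, two-sided, at 20 or more reads in each library. Each family was adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Log2 ratios are of replicate 2 over replicate 1 on CPM + 1, and their counting SE is computed from the read numbers alone. The biological coefficient of variation is the square root of the common dispersion from edgeR with an intercept-only design and TMM scaling. DESeq2 was used for its size factors. A gene list was scored when 3 or more members had at least 10 reads in total, by the percentile of its median log2 ratio among 10000 random lists of its size matched on mean expression in 20 bins.

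A cassette exon was an internal exon flanked by introns whose outer splice sites were also joined directly in other reads, with 5% to 95% inclusion over both libraries. Inclusion is the reads with the exon over those plus the reads that join the flanking sites. Microexons of 3 to 27 nt were compared with longer cassette exons by 100000 permutations of the exons. The major transcript of a gene was the one with the most reads.

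The gene lists covered 8 cell classes, neighbouring tissues (choroid plexus, meninges, blood, striatum, hippocampus, thalamus), state genes (immediate early, heat shock, aged glia), and functions. The functions were presynaptic, postsynaptic, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, imprinted and neurodegeneration-associated genes. X-linked and Y-linked sex genes and a panel of 76 genes with known alternative splicing completed them. The rule for naming genes took up to 4 members per list by mean CPM and all sex genes, the 10 genes with the highest CPM, and the 5 called genes on each side with the largest ratio at 50 or more reads. It also took the 10 genes with an unannotated major transcript that have the most reads, 15 panel genes by reads with at least 2 transcripts over 5%, up to 15 panel genes by reads with a cassette exon between 10% and 90%, and the 10 microexons with the most reads in that range. Not every gene that the rule takes is printed. Genes named outside the rule are said to have been named after their values were seen.

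The binomial and Fisher tests, the list score and the coefficient of variation were tested on simulated data. For the tests and the list score, counts were drawn with sampling error only, so error rates under a larger spread are not shown. With 200 genes changed, the binomial test called 17.5% of genes changed 1.5-fold (9126 genes tested), 49.5% of those changed 2-fold (9083 genes) and 98.0% of those changed 4-fold (9076 genes). In those runs it also called 0, 4 and 15 unchanged genes. The transcript share test called 29.5% of genes shifted by 20 points and 81.0% of those shifted by 40 points, over 5961 genes, and 2 and 4 unchanged genes. The exon test called 24.5% and 77.5% of exons shifted by the same amounts, over 1747 exons, and 0 and 4 unchanged exons. The list score put 5.5% of unshifted lists and 75.0% of lists shifted 1.25-fold outside the range, drawn from 11277 genes. A simulated coefficient of variation of 0.1 was estimated as 0.0959 over 8445 genes.

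Alternatives fixed before the data were examined changed read minimums, pseudocounts, scaling (TMM and DESeq2 size factors), transcript classes counted, mitochondrial genes and the definition of skipping, and left out each library. The use of multi-exon reads only for genes and lists was added after seeing the data. The main matching of transcripts, without class, was also chosen after results were seen, and the first form, with class, is the alternative to it. No contrast between conditions was tested, since the labels give 1 group. Sequence-based checks of splice sites were left out because they need a genome sequence that was not used here. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.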

Results

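RNA of the left cerebral cortex of aged mice was read as long complementary DNA molecules. A read can thus span most or all of a transcript and show which exons were joined in it. The animals were B6CASTF1/J, a hybrid of a laboratory strain and a wild-derived castaneus strain, aged 18 to 20 months, and 2 µg of RNA was used per library. There were 2 libraries in 1 group, numbered by the labels as biological replicates 1 and 2, with the same donor entry. The labels named no treatment, genotype or time contrast, so the data answer which genes and transcript forms this tissue held and how closely the libraries matched. Replicate 1 held 871524 reads and replicate 2 held 839150, of which 774629 (88.9%) and 679147 (80.9%) lay on annotated genes. Single-exon models, which show no joined exons, held 20.6% and 28.7% of mouse reads. With at least 10 reads, 9227 and 9133 annotated genes were detected. A gene with 0 reads could have a level of up to 3.87 CPM, the reads scaled to a common total of reads on annotated genes, in replicate 1 and 4.42 CPM in replicate 2. Intervals and these limits cover counting error only. No label states that the libraries came from separate animals, so SDs measure only the spread between these samples, which may be technical, and p-values of tests between the libraries cover counting error only. Every test between the libraries compares them as sequenced, not conditions.

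Apoe, the main lipid carrier made by astrocytes, was among the most abundant genes at 5638 ± 262 CPM (SD, n = 2; chromosome 7, 19696109 to 19698267, mm10), as was the ubiquitin gene Ubb at 5206 ± 505 CPM. Calm2 stood at 4841 ± 298 CPM, Ptgds, a prostaglandin synthase abundant in the leptomeninges and oligodendrocytes, at 4357 ± 1125 CPM, and Cpe, a peptide-processing enzyme of secretory granules, at 3567 ± 130 CPM. The energy enzymes Aldoa and Ckb, the synaptic vesicle fusion gene Snap25 and the ferritin gene Fth1 were also among them, at 3533 ± 163, 3394 ± 569, 3080 ± 156 and 3059 ± 68.0 CPM. Long intergenic non-coding genes held 0.446% of the reads on annotated genes in replicate 1 and 0.598% in replicate 2, processed pseudogenes 1.03% and 0.964%, and mitochondrially encoded genes 0.124% and 0.108%.

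Markers of all 8 cell classes examined were present in both libraries. The sum of a list depends on the genes it holds, so the order of sums does not rank cell classes by abundance. Astrocyte markers had the highest summed level, 5353 ± 138 CPM over 12 genes, led by Aldoc at 2440 ± 98.2 CPM, Clu at 627 ± 27.1 CPM and the gap junction gene Gja1 at 469 ± 62.0 CPM. Oligodendrocyte markers summed to 2527 ± 286 CPM, with the myelin gene Mbp at 1379 ± 156 CPM. Excitatory neuron markers summed to 1841 ± 63.4 CPM, led by the vesicular glutamate transporter Slc17a7 at 1058 ± 120 CPM and Camk2a at 209 ± 49.6 CPM. Inhibitory neuron markers summed to 1269 ± 100 CPM, led by the GABA-synthesizing enzyme Gad1 at 415 ± 39.3 CPM, Lamp5 at 321 ± 55.8 CPM and the neuropeptide gene Npy at 123 ± 13.9 CPM. Microglia markers summed to 961 ± 9.46 CPM, with the complement gene C1qa at 101 ± 3.27 CPM. Endothelial markers summed to 464 ± 75.6 CPM, with the tight junction gene Cldn5 at 218 ± 65.3 CPM. Oligodendrocyte precursor and mural cell markers were lower, at 212 ± 1.73 CPM and 173 ± 13.2 CPM. The precursor marker Pdgfra had 28.6 ± 7.52 CPM and the pericyte marker Rgs5 had 50.2 ± 14.4 CPM.

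Among markers of neighbouring tissues, those of the striatum had the highest summed level, 844 ± 75.3 CPM, with Ppp1r1b at 364 ± 19.7 CPM and Penk at 213 ± 26.0 CPM. Globin and other blood genes summed to 353 ± 152 CPM. Hippocampus markers summed to 285 ± 1.16 CPM, of which Wfs1 held 262 ± 3.93 CPM, while the dentate gyrus gene Prox1 had 3 and 1 reads. Meningeal fibroblast markers summed to 109 ± 18.1 CPM, thalamus markers to 49.7 ± 11.9 CPM and choroid plexus markers to 27.6 ± 14.0 CPM. The choroid plexus gene Ttr had 18 and 5 reads, and Folr1, Aqp1 and Otx2 had 0 reads in both libraries. The thalamus genes Gbx2 and Zic1 and the hippocampus gene Dsp also had 0 reads in both.

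**Figure D1:**
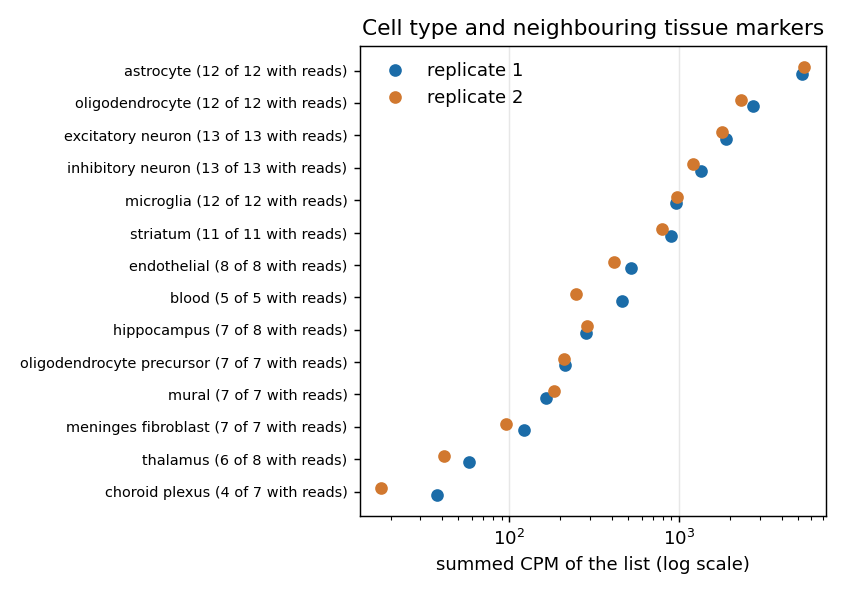
Summed level of each marker list in CPM (log axis) for replicate 1 (blue) and replicate 2 (orange), with the number of list members that had any read. Astrocyte markers stand highest at 5353 CPM on average and choroid plexus markers lowest at 27.6 CPM.

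Most reads came from transcripts whose full splice pattern is annotated, 64.1% of mouse reads in replicate 1 (95% Wilson interval 64.0 to 64.2) and 55.6% in replicate 2 (55.5 to 55.8). Incomplete splice matches, models that match part of an annotated transcript, some of them with a single exon, took 10.4% and 10.1%. New combinations of annotated splice sites took 5.89% ± 0.154 (SD, n = 2), models with an unannotated splice site 3.60% and 3.67%, and models that overlap a gene without matching its splicing, classed as genomic, 6.21% and 6.79%. Intergenic models held 0.841% and 1.08%. Antisense models, lying opposite an annotated gene, held 8.87% in replicate 1 and 16.9% in replicate 2, a ratio of 1.91. Of these antisense reads, 2.75% and 2.63% were on models with more than 1 exon, against 87.6% and 86.3% of the reads on annotated genes. The loci with the most antisense reads lay opposite Gm26917, with 6946 and 13543 reads, Snhg11, a small nucleolar RNA host gene, with 2137 and 4965, and the astrocytic glutamate transporter Slc1a2, with 2092 and 2857. The orientation of reads is not stated, so antisense assignments are uncertain.

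**Figure D2:**
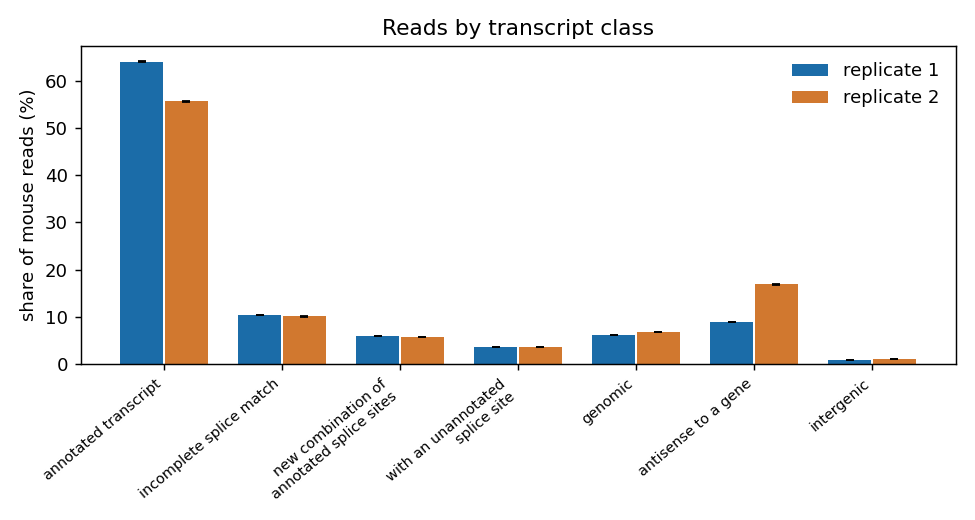
Share of mouse reads in percent by class of transcript model in replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. Annotated transcripts hold 64.1% and 55.6%, and antisense models 8.87% and 16.9%.

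Gene levels in the libraries correlated with a Pearson r of 0.930 on log2(CPM + 1), across 11277 genes with at least 10 reads, which are not independent replicates. The biological coefficient of variation between the libraries was 0.0978 over 8347 genes (edgeR). The chi-square of the counts over genes was 1.79 per degree of freedom, above the 1 that sampling alone would give.

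Of 9143 genes with at least 20 reads, 182 differed between the libraries by an exact binomial test with Benjamini-Hochberg adjustment, 115 higher and 67 lower in replicate 2, and 1075 had an unadjusted p under 0.05. The share of higher calls depended on the scaling, 63.2% with the library totals, 51.6% with TMM and 37.0% with DESeq2 size factors. Among the most abundant genes, Ptgds was lower in replicate 2 (log2 ratio -0.53, counting SE 0.04), as was the brain creatine kinase gene Ckb (-0.34, SE 0.04), and Ubb was higher (0.20, SE 0.03). Calm2 was higher (0.13, SE 0.03), a call lost with TMM (0.09) and DESeq2 scaling (0.05), and Aldoa passed as lower with DESeq2 scaling (-0.17). Of the called genes, 80 were over 2-fold and 19 over 8-fold apart. With the library totals, those annotated as antisense genes were higher in replicate 2 in 15 of 16 cases, long intergenic non-coding genes in 7 of 8, protein-coding genes in 81 of 139 and processed pseudogenes in 3 of 10. With reads of annotated transcripts only, 55 genes differed, and with reads of multi-exon transcripts only, a setting chosen after seeing the data, 78.

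Several of the largest differences among genes with at least 50 reads were at loci with overlapping genes or at processed pseudogenes, where the assignment of reads is uncertain. Higher in replicate 1 were Pcdhga2, of the clustered protocadherins, with 62 reads against 0 (chromosome 18, 37668953 to 37841870), Gm45837 with 118 against 1 (chromosome 7, 101410886 to 101512814) and Gm49450 with 112 against 2 (chromosome 15, 98932137 to 98953551). The processed pseudogene Gm6969 had 50 and 15 reads (log2 ratio -1.51, counting SE 0.42; adjusted p = 0.00940, exact binomial test with Benjamini-Hochberg adjustment). Gm21887 had 50 and 18 reads (-1.25, SE 0.40), a call lost when genes with 10 or more reads were tested. Higher in replicate 2 were Klhl10, known from the testis, with 3 against 230 reads (chromosome 11, 100441089 to 100461670), and Arap1 with 12 against 126 (3.50, SE 0.44), whose interval on chromosome 7 (101348067 to 101512817) overlaps that of Gm45837. At the Klhl10 locus, same-strand models of an unannotated gene held 222 reads in replicate 1. The pseudogenes Oaz1-ps and Gm11223 had 10 against 53 and 34 against 132 reads (2.51, SE 0.50, and 2.12, SE 0.28). The long non-coding gene 2310075C17Rik had 50 against 158 reads (1.83, SE 0.23).

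**Figure D3:**
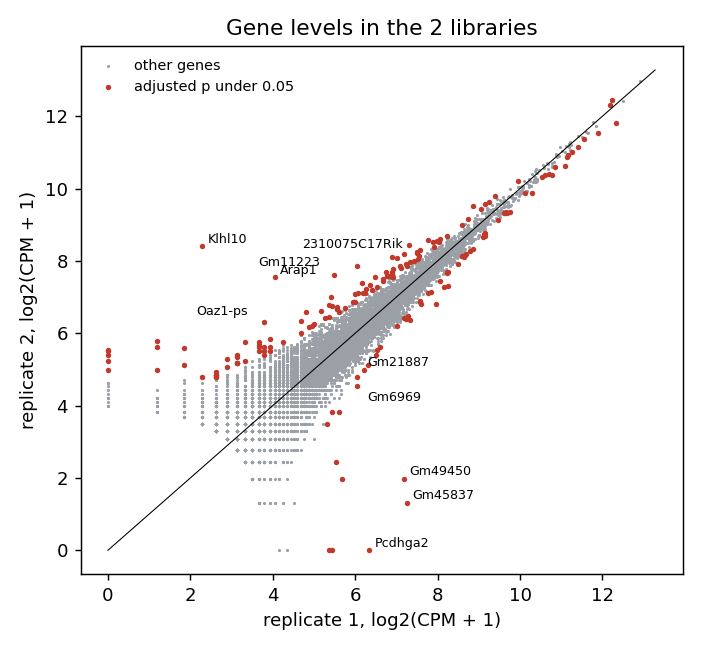
Level of each gene with at least 10 reads in replicate 1 (x axis) and replicate 2 (y axis), as log2(CPM + 1), with the 182 genes that differed by the exact binomial test in red and the line of equal levels in black. The 10 named genes are the 5 on each side with the largest log2 ratios among called genes with at least 50 reads.

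Between the libraries, 7 of 24 gene lists fixed before the data were examined had a median log2 ratio outside the central 95% of 10000 random lists matched on expression. This describes these libraries and is not a test of conditions. Blood genes were the farthest, with a median of -0.87, below each of the random lists. Of the 4 measured, Hba-a1, an alpha-globin gene, fell from 249 to 112 CPM (log2 ratio -1.15, counting SE 0.20) and 3 did not pass. The globin genes share near-identical copies, so their split is uncertain. Adjusted over the list alone, 3 blood genes passed. Striatum genes had a median of -0.49 (percentile 0.14), with 9 measured and 7 tested, of which 0 passed either over all genes or adjusted over the list alone. Oligodendrocyte genes had a median of -0.29 (percentile 0.6), with 10 measured. Among them Mbp (log2 ratio -0.23, SE 0.06) and the iron carrier Trf (-0.53, SE 0.12) fell, and 8 did not pass, including Cnp (0.04, SE 0.15). Adjusted over the list alone, 2 passed. The call for Mbp was lost with reads of annotated transcripts only, at a ratio of -0.22.

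Nuclear-encoded oxidative phosphorylation genes had a median of -0.21 (percentile 0.17, 16 measured). Ndufa4 fell (log2 ratio -0.36, counting SE 0.09), a call lost with reads of annotated transcripts only (-0.07), 15 did not pass, including Cox4i1 (0.03, SE 0.05), and 5 passed when adjusted over the list alone. Cox8a passed as lower with TMM (-0.29) and DESeq2 scaling (-0.33). Genes of aged glia had a median of -0.22 (percentile 2.25, 15 measured, 14 tested), with 0 called over all genes and 1 adjusted over the list alone. The list was back inside the range with pseudocount 0.1 (percentile 2.52), with TMM (2.59) and with reads of annotated (8.37) or of multi-exon transcripts only (7.38). Apoe was at -0.09 (SE 0.03), and passed as lower with TMM (-0.13) and DESeq2 scaling (-0.17), and the antigen-presentation gene B2m at 0.08 (SE 0.28). Postsynaptic genes had a median of 0.32 (percentile 99.99, 22 measured, 21 tested). The NMDA receptor gene Grin1 (0.41, SE 0.11) and the scaffold gene Homer1 (0.76, SE 0.18) rose and 19 did not pass, among them Nrgn (0.05, SE 0.05), with 2 adjusted over the list alone. The Grin1 call was lost with DESeq2 scaling (0.34) and with reads of annotated (0.25) or of multi-exon transcripts only (0.39). The panel of genes with known alternative splicing had a median of 0.08 (percentile 99.1, 76 measured, 74 tested), with Grin1 and Homer1 higher, Mbp and the glycolytic gene Pkm (-0.24, SE 0.05) lower, and 4 adjusted over the list alone. With reads of annotated transcripts only, 2 of these 7 lists, blood and the splicing panel, stayed outside the range, and 5 of 23 lists in all were outside.

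The other 17 lists lay inside the range. In the astrocyte list, 1 of 12 tested genes fell, the filament gene Gfap (log2 ratio -0.89, counting SE 0.17), and 1 passed adjusted over the list alone. In the endothelial list, 1 of 6 tested genes fell, Cldn5 (-0.62, SE 0.17), with 1 adjusted over the list alone, and the call was lost with reads of annotated transcripts only (-0.55). Of 11 immediate early genes tested, Arc (0.45, SE 0.13) and Egr3 (0.78, SE 0.21) rose and 3 passed adjusted over the list alone. The Arc call was lost with TMM (0.41) and DESeq2 scaling (0.37), and Egr3 had a ratio of -0.01 on multi-exon reads. Of 8 heat shock genes tested, Hspa8 fell (-0.16, SE 0.05), a call lost with reads of annotated (-0.13) or of multi-exon transcripts only (-0.15), and 2 passed adjusted over the list alone. Of 19 presynaptic genes tested, Syn1 (0.38, SE 0.10) and the active zone gene Bsn (0.94, SE 0.24) rose, with 2 adjusted over the list alone. The Syn1 call was lost with DESeq2 scaling (0.30) and the Bsn call with multi-exon reads, at a ratio of 1.60. Syp (-0.22) and Snap25 (-0.18) passed as lower with DESeq2 scaling, as did Ndrg4 of the splicing panel (-0.15). Of 18 imprinted genes tested, the maternally expressed non-coding gene Meg3 rose (0.65, SE 0.10), with 1 adjusted over the list alone. The Meg3 call was lost with reads of annotated transcripts only (log2 ratio 0.59) and of multi-exon transcripts only (0.41). Gfap, Egr3, Syn1, Bsn and Homer1 were named after their values were seen.

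With the library totals, no tested gene passed over all genes in the remaining lists that were scored; medians are over measured genes and counts over tested ones. Adjusted over the list alone, 2 of 11 excitatory neuron genes (median -0.21), 2 of 11 inhibitory neuron genes (median -0.20) and 1 of 11 mitochondrially encoded genes (median -0.19) passed. The count adjusted over the list alone was 0 for 8 tested microglia genes (median -0.18), 4 oligodendrocyte precursor genes (0.17), 3 mural genes (0.55), 3 meningeal fibroblast genes (0.02) and 1 hippocampus gene (0.17). It was also 0 for 1 tested thalamus gene (-0.40), 21 genes associated with neurodegeneration (-0.05) and 5 X-linked sex genes (-0.20). With other scalings Slc17a7 passed as lower (-0.27 with TMM, -0.31 with DESeq2), as did mt-Rnr2 with DESeq2 (-0.72) and Apoe of the neurodegeneration list with both. The transcripts of App and Prnp, from the neurodegeneration list, stood at 1018 ± 46.5 and 1756 ± 70.3 CPM. The choroid plexus list, with 2 measured genes, and the Y-linked list, with 0, were not scored.

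**Figure D4:**
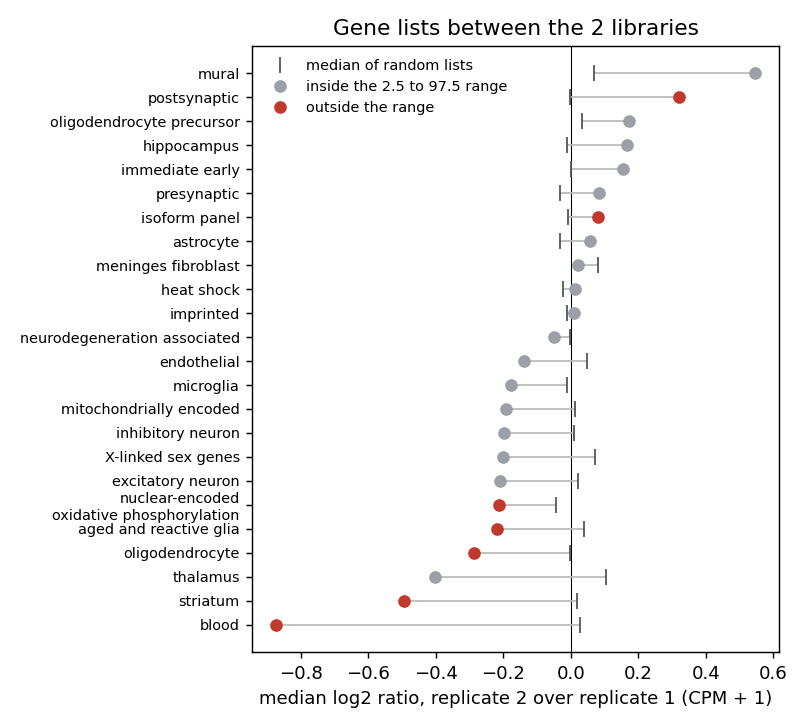
Median log2 ratio of each gene list, replicate 2 over replicate 1 on CPM + 1 (points), joined to the median of random lists matched on expression (ticks). The 7 lists in red lie outside the central 95% of the random lists, from blood at -0.87 to postsynaptic genes at 0.32.

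The share of the major transcript of each gene correlated between the libraries with an r of 0.918 across genes, which are not independent replicates. By Fisher's exact test with Benjamini-Hochberg adjustment, 10 of 5961 genes differed in the share of their major transcript, and 401 had an unadjusted p under 0.05. The annotated transcript Tuba1a-201 of an alpha-tubulin gene fell from 97.2% to 91.3% of Tuba1a reads, as the reads of its other transcripts went from 51 to 142. This call is uncertain, because the overlapping gene Gm49450 had 112 reads in replicate 1 and 2 in replicate 2. Ckb-201 fell from 89.1% to 84.6%. Tsc22d3-201, of a glucocorticoid-induced gene, rose from 37.5% to 69.3%, and Gnb1-201 from 41.8% to 56.9%. Pabpn1-201 fell from 66.7% to 34.9%, Ptprn-201 from 34.1% to 19.8%, Rab24-201 from 75.6% to 50%, and Camk1-201 from 88.2% to 72.0%. In Gprasp1 and Pde8b the pooled single-exon unannotated models went from 40% to 2.27% and from 1.41% to 28.7%. These 10 genes were named after their values were seen. Of the 66 genes of the splicing panel that were tested, 0 differed over all genes and 0 adjusted over the list alone. Of the 10 calls, 1 was left with annotated transcripts only, and 1 when incomplete splice matches and genomic models were left out. The count rose to 112 when models were matched by class as well as by intron chain, the matching used before the first results were seen and replaced afterwards.

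Genes of the splicing panel named here were chosen for having at least 2 transcripts over 5% of their reads, with none called between the libraries. The pool of single-exon unannotated models counted as a transcript in that choice, as in Map4. The largest shifts among them included Cltb-202, at 9.30% and 15.9% of Cltb reads, and the pooled single-exon models of Camk2b, at 35.5% and 28.0%. Snap25-201 held 79.4% ± 1.71 (SD, n = 2) of Snap25 reads and Snap25-202 held 9.49% ± 0.595. Pkm-202 held 78.8% ± 1.76 of the reads of the pyruvate kinase gene, and Mbp-211 held 55.9% ± 3.77 and Mbp-212 held 12.9% ± 1.45 of Mbp reads. Cdc42-201 and Cdc42-202 of the cytoskeletal GTPase gene held 35.2% ± 4.32 and 28.6% ± 3.44. Gnao1-203, Gnao1-201 and Gnao1-212 of the Go alpha subunit gene held 32.6% ± 0.149, 26.6% ± 0.0355 and 18.3% ± 0.651. Ndrg4-202 held 37.1% ± 1.98, Ndrg2-202 held 36.6% ± 2.53, Map4-206 held 57.5% ± 2.10 and Cltb-201 held 58.3% ± 3.94 of the reads of their genes. In Tpm3, a tropomyosin gene, an unannotated combination of annotated splice sites with 8 exons held 66.5% and 70.1%. Pooled single-exon unannotated models held 73.0% ± 4.50 of Slc1a2 reads and 29.2% ± 1.63 of Grin1 reads.

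In 945 of 6116 genes (15.5%, 95% Wilson interval 14.6 to 16.4) the most abundant transcript was unannotated in both libraries. In 346 of them it had the same intron chain in both, and in 471 it had a single exon in both. By class, 325 were genomic, 210 incomplete splice matches, 175 new combinations of annotated splice sites and 34 models with an unannotated splice site, and 201 differed in class between the libraries. Nrgn, a calmodulin-binding postsynaptic gene, had the most reads among them. On the minus strand of chromosome 9, a 3-exon model from 37544492 to 37552904 held 93.0% ± 0.518 (SD, n = 2) of Nrgn reads. The 5′ end of that model lay upstream of the annotated 5′ end of the gene at 37552533. In Oaz1, which controls polyamine synthesis, a 5-exon model held 95.2% ± 1.73, and in Apbb1, which encodes a binding partner of the amyloid precursor protein, a 14-exon model held 56.8% ± 4.19. A 10-exon model of the transcriptional corepressor gene Ctbp1 held 58.0% ± 2.84. Incomplete splice matches with several exons led in Pink1 (59.6% ± 3.42), Pld3 (77.0% ± 2.48) and Nell2 (58.4% ± 0.381). Single-exon models led in Gabarapl1 (67.4% ± 2.95), Clstn1 (27.2% ± 0.346) and AC149090.1 (42.0% ± 0.221), a gene on an unplaced scaffold with uncertain assignment. The leading model was not the same in replicates 1 and 2 for Clstn1 (2134 and 1527 nt) and AC149090.1 (502 and 2871 nt).

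Unannotated spliced models recurred between the libraries according to their read number. Of the intron chains with a new combination of annotated splice sites or an unannotated splice site, 70.2% ± 0.161 (SD, n = 2) of those with at least 2 reads in a library had at least 1 read in the other. The share was 27.3% ± 0.420 for chains with at least 1 read, 97.1% for at least 5 and 99.9% for at least 10. At 2 reads it was 74.1% ± 1.41 for new combinations and 62.5% ± 1.78 for chains with an unannotated splice site.

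Cassette exons were measured as the percent of informative reads that included the exon, for 1747 exons of 1203 genes with at least 20 informative reads in each library. Between 10% and 90% inclusion in both libraries were 873 exons of 656 genes. Snap25 held its mutually exclusive exon pair at 89.2% ± 0.238 (SD, n = 2; chromosome 2, 136770057 to 136770174) and 10.8% ± 0.334 (136769743 to 136769860). The alternative pair of the AMPA receptor gene Gria2, both exons 115 nt, stood at 55.6% ± 0.567 and 45.6% ± 1.47 (chromosome 3, 80690404 to 80690518 and 80691320 to 80691434). In Grin1 the C-terminal cassette of 111 nt was included in 54.5% ± 1.13 of reads (chromosome 2, 25294438 to 25294548) and the N-terminal cassette of 63 nt in 27.2% ± 6.29 (25311343 to 25311405). The Mbp exons of 123 and 78 nt were included in 19.5% ± 2.09 and 11.3% ± 0.781. A 39 nt exon of Ndrg4 stood at 82.7% ± 1.18, a 42 nt exon of Ndrg2 at 34.8% ± 3.00, and a 54 nt exon of the clathrin light chain gene Cltb at 82.1% ± 5.80. The endocytosis gene Bin1 included exons of 108 and 93 nt at 34.1% ± 1.99 and 84.1% ± 2.35. The mitochondrial fission gene Dnm1l included exons of 33 and 39 nt at 82.2% ± 0.190 and 48.0% ± 7.91, and Camk2d exons of 89 and 42 nt at 37.5% ± 2.97 and 74.8% ± 4.21.

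Inclusion correlated between the libraries with an r of 0.971 across exons, which are not independent replicates. A single exon, the 57 nt coding exon of Eef1d, a translation elongation factor gene (chromosome 15, 75897226 to 75897282), differed, with 46.3% (34.9 to 58.1) in replicate 1 and 7.69% (2.65 to 20.3) in replicate 2 (adjusted p = 0.0482, Fisher's exact test with Benjamini-Hochberg adjustment). It was named after its values were seen, and 63 exons had an unadjusted p under 0.05. The call was absent, with 0 exons differing, under each of the 4 other settings for exon counting. Of the 725 coding exons between 10% and 90%, 465 had a length that is a multiple of 3 (64.1%, 95% Wilson interval 60.6 to 67.5).

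**Figure D5:**
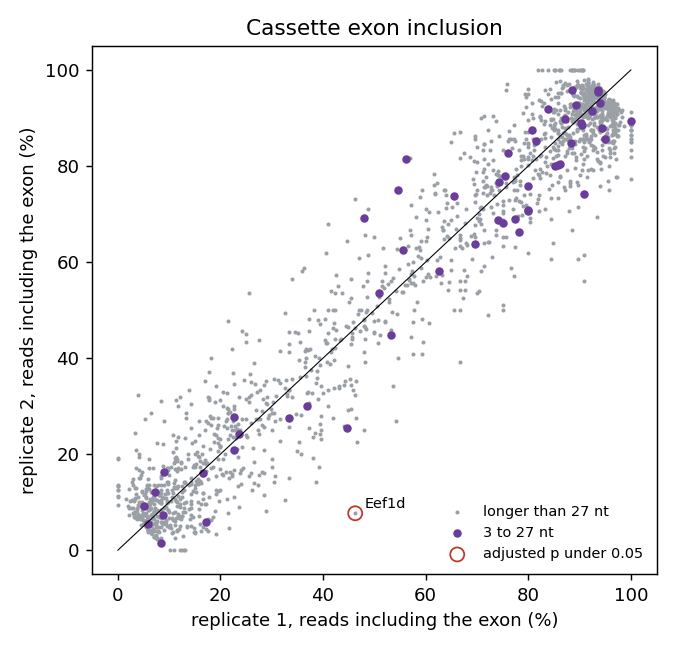
Percent of informative reads that include each of 1747 cassette exons in replicate 1 (x axis) and replicate 2 (y axis), with the 53 exons of 3 to 27 nt in purple and the line of equal inclusion in black. The points follow the line with an r of 0.971, and the circled exon of Eef1d was the 1 that differed.

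Microexons, of 3 to 27 nt and known to be used mainly in neurons, numbered 53, of which 47 had a length that is a multiple of 3. Those with the most reads between 10% and 90% were a 25 nt exon of Cd47 at 86.5% ± 2.58 (SD, n = 2; chromosome 16, 49908054 to 49908078), an 18 nt exon of the actin regulator gene Nckap1 at 52.3% ± 1.82 (chromosome 2, 80571213 to 80571230) and a 27 nt exon of the phosphatase gene Ptpra at 59.0% ± 5.01 (chromosome 2, 130509830 to 130509856). Exons of Pls3 (27 nt), Anxa6 (18 nt), the dynactin gene Dctn1 (21 nt) and Hnrnpc (26 nt) stood at 72.2% ± 8.36, 75.5% ± 1.70, 76.8% ± 1.76 and 88.4% ± 1.84. Exons of Nrbp1 (24 nt) and Mark3 (27 nt) stood at 35.0% ± 13.7 and 25.2% ± 3.61. The median inclusion of microexons was 75.5% and 73.8% in replicates 1 and 2, against 66.7% and 65.6% for longer cassette exons. The differences of 8.87 and 8.15 points were within what permuting the exon lengths gave (two-sided permutation p = 0.453 and 0.521), and exons are not independent replicates.

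Sex-linked genes were examined because the labels give the sex as female in the sex field and as male in the free-text description of both libraries. Xist, the RNA that coats the inactive X chromosome, had 34 and 29 reads (43.3 ± 0.842 CPM, SD, n = 2). None of these lay on an annotated Xist transcript, 2 and 3 were on spliced models, and 29 and 23 were on a single-exon model at the gene's 5′ end (chromosome X, 103482788 to 103483254 in replicate 1). Its antisense partner Tsix, which overlaps it, had 15 reads in each library (20.7 ± 1.93 CPM), so the split between the pair is uncertain where they overlap. The single-exon Xist model lay at the edge of that overlap, as the annotated Tsix gene ends at 103482789. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in both libraries, which allows up to 3.87 and 4.42 CPM. Their X-linked counterparts were detected, Ddx3x at 40.1 ± 10.9 CPM, Eif2s3x at 79.1 ± 14.1 CPM, Kdm5c at 28.9 ± 0.741 CPM and Kdm6a at 12.7 ± 7.57 CPM. The 0 reads on all 4 Y-linked genes argue against the male label for these libraries. Chromosome Y as a whole held 19 and 27 reads, few of them on annotated genes.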

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

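Of the tests in this part, those of misoriented reads, of a few loci, of overlapping gene names and of length for the oxidative phosphorylation list alone were chosen after the results were seen. No biological explanation was tested for any pattern, since the design gives 1 group.

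Reads outside the comparisons were flagged because they stood above the limit that a count of 0 allows. Spike-in RNAs of the ERCC set had 13617 reads in replicate 1 and 11083 in replicate 2, over 48 species, with an r of 0.991 across the 26 species with at least 10 reads, and 2 of 22 tested species differed between the libraries. Chromosome Y held 19 and 27 reads, of which 3 and 4 lay on annotated genes, although the 4 Y-linked genes of the sex list had 0. The locus with the most antisense reads, opposite Gm26917 on chromosome 17 from 39843013 to 39848035, held 6946 and 13543 reads against 16 and 12 on Gm26917 itself. That interval of mm10 is known to carry a copy of the ribosomal RNA precursor.

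For antisense reads, 1.91 times as frequent in replicate 2, reversed reads that kept their introns are argued against as the main source. At most 2.75% of antisense reads in either library were on multi-exon models, against 86.3% or more of the reads on annotated genes. Reversed reads with a single exon were not tested, and the orientation of reads is not stated, so reversal of reads in general stays open. A few loci are also argued against, because the ratio was 1.96 without the 10 top loci, and 1399 of 1537 loci with at least 20 reads (91.0%) had a higher share in replicate 2. Priming at A-rich stretches stays open: the lower median excess of A beyond model ends over random positions was 0.1, and 42.2% and 41.2% of models had at least 12 A in 20 nt, against 3.41% and 3.60% of random positions. Of the antisense reads tested, 40.2% in replicate 1 and 33.4% in replicate 2 were on such models, so their share within antisense reads was not higher in replicate 2. This is not their share of all mouse reads, of which antisense reads took more in replicate 2. That test did not decide, because the lower excess lay between the limits set beforehand for and against this cause. In addition, only 13.5% and 10.9% of the models had sequence. A-rich priming, reversed single-exon reads and a difference between the tissues or library preparations therefore cannot be told apart.

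For the 19 genes over 8-fold apart, a candidate explanation is that reads of a locus were named for different overlapping genes in the 2 libraries. Such a counterpart was found for 6 of the 19, and for 8 with ends allowed to differ, against 0 of 190 genes within 2-fold. The 190 were matched on read number only, not on having an overlapping gene, so their 0 does not weigh for this explanation. Examples are Gm45837 and Arap1, whose models lay under Pde2a in the other library, Gm49450 under Tuba1a and Klhl10 under an unannotated gene with 222 reads. The top Klhl10 model had 228 reads in replicate 2, so naming can account for the Klhl10 call. The genes with no counterpart each had a single-exon top model. Naming and a true difference between the libraries therefore cannot be told apart for the 19 as a set.

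For the 7 lists outside the range, counting error alone is argued against, because at most 4 lists lay outside in any of 100 random splits of the pooled reads. Transcript length as the whole cause is argued against too, because 4 of the 7 lists (oligodendrocyte, blood, striatum and postsynaptic) stayed outside after adjustment for length, though the postsynaptic median shrank from 0.32 to 0.20. Across genes the log2 ratio rose with length (Spearman's rho 0.150; genes are not independent replicates). For the nuclear-encoded oxidative phosphorylation list alone, length may account for the shift, as its percentile moved to 12.4 and its median from -0.21 to -0.12, and the splicing panel (percentile 95.2, median 0.08 to 0.03) and the aged glia list (percentile 3.38, median -0.22 to -0.23) also moved inside the range. How much meninges, blood or white matter each piece of tissue held stays open, as untested.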

How the results depend on the processing

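The multi-exon settings for genes and lists were chosen after seeing the data, as was the main matching of transcripts, without class. Directions and sides of the threshold were kept in 745 of the 786 recomputed log2 ratios of named genes, 27 lost and 13 gained a call, and Egr3 reversed to -0.0112 on multi-exon reads, with an adjusted p of 1. Depth limits the list: 8802 genes were detected in replicate 1 thinned to 679147 reads. With multi-exon transcripts only, annotated transcripts held 75.7% and antisense models 0.465% of reads. The correlation of gene levels was 0.911 and 0.949 with pseudocounts 0.1 and 5, 0.946 at 50 or more reads, 0.924 with no minimum and 0.939 with annotated transcripts only. The biological coefficient of variation was 0.0974 with library-size scaling, 0.117 without a filter, 0.0812 with annotated transcripts only and 0.0982 with DESeq2 size factors. These 2 values have no replicate spread, so any change was counted as a move. Genes differing numbered 55 with annotated transcripts only, 78 with multi-exon reads only, and from 150 to 243 in the other settings. Genes differing in transcript share numbered 17 at 50 or more reads, 1 with annotated transcripts only (fewer genes tested) and 112 with matching by class, the first form used. Leaving out incomplete and genomic models gave 9, of which 1 was shared. Genes with an unannotated major transcript numbered 379 at 50 or more reads, 585 with incomplete splice matches counted as annotated and 540 without genomic models. Shared unannotated chains were 27.3% and 97.1% at 1 and 5 reads. Exons between 10% and 90% numbered 363 and 1362 at 50 and 10 informative reads and 276 with annotated transcripts only. Differing exons numbered 0 in all 4 settings. Xist was at 0 CPM with annotated transcripts only. With annotated transcripts only, 5 of the 7 lists returned into the range (oligodendrocyte, striatum, aged glia, postsynaptic and oxidative phosphorylation), and the precursor, mural and presynaptic lists left it. The aged glia list also returned into it with pseudocount 0.1, with TMM and with multi-exon reads only. The cause was not tested for any of these beyond what the settings' construction shows. The median difference of microexons from longer exons ranged from -8.40 (up to 50 nt) to 17.1 points (50 or more reads), and the setting of 3 to 15 nt left 1 exon. Leaving out each library gave 55.6% to 64.1% for annotated transcripts, 8.87% to 16.9% for antisense models, 9133 to 9227 genes, 1220 to 1293 genes with an unannotated major transcript, 1058 to 1132 exons and 42.7 to 43.9 CPM for Xist.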

Other observations

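The genes in this part were named after their values were seen. Among long non-coding genes higher in replicate 2, Malat1, abundant in nuclear speckles, rose from 79 to 122 reads (log2 ratio 0.81, counting SE 0.21; adjusted p = 0.00903, exact binomial test with Benjamini-Hochberg adjustment). Miat, also nuclear, rose from 83 to 139 reads (0.93, SE 0.20), a call lost on multi-exon reads, at a ratio of 1.02. Of the protein-coding genes that differed, 81 of 139 were higher in replicate 2. Those lower included the mitochondrial ATP synthase genes Atp5b (-0.45, SE 0.06) and Atp5a1 (-0.41, SE 0.07), the tubulin gene Tubb2a (-0.27, SE 0.05), the autophagy gene Gabarapl1 (-0.39, SE 0.06) and the neuropeptide gene Cck (-0.40, SE 0.09). The calls for Gabarapl1 and Cck were lost with reads of annotated (-0.16 and -0.23) or of multi-exon transcripts only (-0.19 and -0.27). Tuba1b (-0.25, SE 0.06), Actb (-0.31, SE 0.09) and Actg1 (-0.23, SE 0.06) also fell, and their calls were lost with reads of annotated transcripts only, at ratios of -0.21, -0.22 and -0.23. The calls of Actb and Actg1 were also lost with multi-exon reads only, at -0.28 and -0.21. Every one of these 10 calls held with TMM and DESeq2 scaling.

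Antisense reads lay opposite several neuronal genes. The postsynaptic scaffold gene Shank1 had 1177 and 1604 antisense reads against 40 and 39 on the gene itself, and the microtubule-associated gene Map1b had 540 and 763 against 32 and 35. Opposite Cplx2, a regulator of vesicle fusion, they went the other way, with 804 and 521 against 284 and 241. Opposite Lncpint the reads were 150 and 410, 2.83 times as frequent in replicate 2 per mouse read, and opposite AI593442 they were 786 and 780, at a ratio of 1.03.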
